A study of Mus musculus with 28 samples.

How the data were processed

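Gene expression was measured on 28 single-colour (Cy3) Agilent mouse arrays in 14 groups of 2 arrays each. Groups, sexes, stages and replicate numbers were taken from the sample labels. The 4 EG arrays carry the name EG in their titles and a source field that names primordial germ cells, and they were grouped as EG by title. The labels state neither how cells were sorted nor whether cultures were grown on feeder cells, and they do not say whether 2 arrays of a group came from separate animals or cultures. All p-values therefore measure the spread between these samples, which may be technical.

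Per the file headers, spots were quantified with Agilent Feature Extraction 10.5.1.1, which the submitters' processing notes also name. Its processed signal, a background-adjusted intensity on a linear scale, was used as deposited, and no array had a saturated spot. Total RNA was purified with column or phenol reagents from small numbers of cells and labelled by linear amplification, per the labels' protocols. The deposited value table of the whole series holds log2 values whose making is not given in the sources used here. Set against the scanner values, each of its columns equalled log2 of the processed signal minus that array's median, to within 0.0025, with column medians from -7.34e-05 to 0.0025. Its scale, centring and direction were thus all found, and it served as an alternative.

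Values were computed in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8). The 1417 control spots were removed, and so were 514 of the 43803 remaining probes, which were marked non-uniform on at least 1 array. Under 50% of probes were well above background on 16 of the 28 arrays. Each array was therefore scaled by subtracting, from log2 processed signal, its 75th percentile over the 7286 probes that were well above background on all 28 arrays. A level of 0 is thus that percentile of the array.

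Probe accessions were looked up in a RefSeq table of assembly GRCm38.p6, used for names, chromosomes and neighbours only, since the array design carries coordinates of an older build (mm9). Of the probes, 16751 matched 13137 symbols and 27052 did not match, 749 of them with RefSeq-type accessions. For 62 probes the accession differed between design files. The 30631 resulting features are called genes in the text, whether named or not. For the 3148 genes with several probes the probe with the highest mean was kept. The probes of a called gene did not always move together. Of the called genes with several measured probes, a probe with the opposite sign was present in 65 of 688 for E13.5 against E10.5 and in 207 of 948 for GS against spermatogonia.

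A gene entered a comparison where it was well above background on both arrays of at least 1 compared group. The files give no depth other than signal over background. Between 17.8% (E10.5 male replicate 1) and 76.7% (testis replicate 1) of probes were well above background, and the lowest signal that counted as such lay between -10.73 and -3.58 log2 units. Where no probe of a gene was well above background on any array of 1 side, only a bound is printed as "at least N-fold". It sets the bright side's mean against the dim side's mean of, per array, the higher of that lowest signal and the probe's own value. Where only some arrays of the dim side were well above background, the fitted change is printed, and it rests partly on dim values. Medians of a list are also given with such members at their bounds where the median moved. Called genes whose brighter side had no group fully well above background have no order and were not named as highest or lowest. There were 803 such genes for EG against PGC, 142 for oogonia against E17.5 females, 76 for GS against spermatogonia, 59 for E13.5 against E10.5 and 47 for spermatogonia against oogonia.

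A linear model with 1 mean for each of the 14 groups was fitted to all 28 arrays (lmFit and eBayes in limma, 14 residual degrees of freedom), so that all comparisons share 1 estimate of the spread. Benjamini-Hochberg adjusted p under 0.05 was called changed, and each ± after a log2 fold change is its standard error (SE) from this fit. Comparisons were stage and sex in PGC and their interaction, spermatogonia against oogonia, each of these against E17.5 PGC of its sex, EG against PGC (4 EG arrays against the 8 arrays at E10.5 and E13.5), EG against ES, sex in EG and in ES, GS against spermatogonia and GS against testis. An X-linked shift is the median log2 difference, male minus female, of X-linked genes minus that of autosomal genes, over genes well above background on all 4 arrays. EG and ES sex differences were compared by an interaction that was added after the data were examined.

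The comparisons, alternatives and the rule for named genes were fixed before the data were examined, and the entries of the 23 gene lists were written then too. Some entries are name prefixes, and after the first run the X-linked testis and Rhox lists were restricted to genes on chromosome X, since prefixes had also caught genes elsewhere. The lists are pluripotency, early germ cell specification, germ cell and genome defence, meiotic prophase, oocyte, fetal male germ cell and piRNA, spermatogonial, spermatocyte and spermatid, Sertoli and pregranulosa, Leydig and steroidogenic, blood and endothelium, mesenchyme and fibroblast, X-linked testis and multicopy, Rhox cluster, Y-linked, X escape and Xist, imprinted maternally expressed, imprinted paternally expressed, DNA methylation machinery, histone repressive marks, proliferation, Hox, and immediate early and heat shock. Some genes stand in 2 lists: Rhox5 (Sertoli and Rhox), Thy1 (spermatogonial and mesenchyme), Taf7l (germ cell and X-linked testis), Akap4 (spermatocyte and X-linked testis), Dnmt3a and Dnmt3l (fetal male and DNA methylation). Each list was set against all other tested genes with camera at its preset correlation of 0.01, and again with a correlation estimated from the data, with p adjusted over the lists of a comparison. In fry, a list's genes were tested for moving on balance in 1 direction. A list's members were also adjusted over the list alone.

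Genes are named by a fixed rule. For each list described, up to 4 called members with the largest change are named, or the 1 with the largest change where none was called. Added to these are the 5 highest and 5 lowest called changes among genes with a symbol whose arrays did not overlap between the sides and whose higher side was well above background on all arrays. The text prints a part of the genes so chosen, and 2 of the others are not reported here. Levels are given per group for 11 genes: Xist, Ddx3y, Eif2s3y, Pou5f1, Dppa3, Ddx4, Dazl, Stra8, Nanos2, Dnmt3l and Prm1.

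The arrays lay on 9 slides scanned on 6 days. The PGC arrays lay on 4 slides over 2 days, with replicate 1 of each PGC group scanned on day 1 and replicate 2 on day 2. Same-numbered PGC arrays deviated together from their group means in all 15 pairs of groups (r from 0.29 to 0.80, median 0.45, across 5411 genes, which are not independent), so the number marks the scan day there and pairs these arrays. Over all 14 groups it did not: 30 of 91 pairs had r over 0.1, with a median of 0.03. For PGC, values with slide as a block (12 arrays), with scan day as a block and within each day stand beside the results. EG sex, ES sex and GS against testis lie within 1 slide each. For the other comparisons each group lies on slides of its own, so slide, scan day and group cannot be told apart. Slide as a random block (correlation within slides 0.606) is an alternative there.

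Alternatives chosen before the data were examined were quantile normalization, normexp background correction (offset 50), the deposited log2 values, no filter on dim probes and a stricter one (8 arrays), the mean over a gene's probes, eBayes with trend and robust, only the compared groups in the fit, slide as a fixed and as a random block, the replicate number as a block, a 2-fold minimum, other sets of X-linked genes and leaving out each replicate. The files carry no mean signal column, so normexp ran on the median signal and the median background. Added after the data were examined were the percentile over all probes, a filter on any of the 14 groups, scan day as a block, a common floor at the highest detection limit, and a fit without E10.5 male replicate 1, EG female replicate 2 and GS replicate 1.

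The steps were tested on simulated data with known changes. The simulated noise was independent between arrays, with the same spread for a gene in all groups. It held no correlation within slides or scan days, so the shares below need not hold for the real arrays. For E13.5 against E10.5 (11645 genes), 40.3% of genes changed 2-fold were recovered, 85.1% of those changed 4-fold and 97.0% of those changed 8-fold, and 2 of 11180 unchanged genes were called. For male against female PGC at E13.5 (11553 genes) the shares were 10.4%, 62.7% and 89.4%, with 2 of 11091 unchanged genes called. Of 67 genes changed 2-fold in GS against testis (24177 genes) 0 were called by limma, against 35.8% at 4-fold and 69.7% at 8-fold, and 4 of 23550 unchanged genes were called. A true X-linked shift of -0.5 was estimated as -0.49 in the E13.5 sex comparison, where an unshifted list of 20 genes also fell under camera's unadjusted threshold of 0.05. It did not do so in the other three simulated comparisons.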

Results

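The series title concerns DNA methylation in mouse primordial germ cells (PGC), the embryonic precursors of eggs and sperm, and these 28 arrays give gene expression in the same kinds of cell. PGC came from female and male embryos at 10.5, 13.5 and 17.5 days post coitum (E10.5, E13.5, E17.5). They were set beside oogonia and spermatogonia (female and male germ cells of unstated age), female and male EG cells (pluripotent lines derived from PGC), female (line no5) and male (line TMA5) ES cells, GS cells (cultured spermatogonial stem cells) and adult testis. Each of the 14 groups had 2 arrays. Strains differed between the PGC, the oogonia and spermatogonia, and each cell line or tissue, ES males and females included. Between 17.8% (E10.5 male replicate 1) and 76.7% (testis replicate 1) of probes were well above background, and the number of arrays limits the precision.

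Levels of 11 genes fixed beforehand separated the cell types. Eif2s3y, a Y-linked translation factor, lay between -3.26 and -1.89 (means of 2 arrays, log2 relative to each array's 75th percentile) in every male group and between -10.60 and -6.91 in every female group, which matched the sex labels. ES females were well above background for it on both arrays (-6.91 ± 0.21, SD, n = 2) and for Ddx3y, a Y-linked RNA helicase (-8.29 ± 0.03), both far below ES males (-2.32 ± 0.21 and -4.81 ± 0.41). Xist, the RNA that coats the inactive X chromosome, was higher in E17.5 females (-3.93 ± 1.26) than in E17.5 males (-5.82 ± 1.42), and so it was on each scan day (-4.82 against -6.82 and -3.05 against -4.81), short of the threshold (limma adjusted p = 0.0741). GS arrays, from males, held -3.32 and -5.86. Pou5f1, the core pluripotency factor, lay at 3.94 to 4.13 in EG cells, 3.95 to 4.07 in ES cells and 3.04 to 4.25 in PGC at E10.5 and E13.5. It lay at -2.54 ± 0.68 in E17.5 females and 2.11 ± 0.79 in E17.5 males. Dppa3, a maternal factor also made by early PGC, was highest in oogonia (3.26 ± 0.07) and lay at -4.51 ± 0.09 in spermatogonia. The germ cell RNA-binding genes Ddx4 and Dazl lay at 1.12 ± 0.10 and 2.10 ± 0.01 in oogonia, and at -5.50 ± 0.42 and -4.71 ± 2.27 in EG females. Stra8, the retinoic-acid target that opens meiosis, peaked in E13.5 females (3.09 ± 0.33) and was well above background in GS cells (0.84 ± 0.64). Nanos2, a repressor of meiosis in the male germ line, peaked in E13.5 males (-0.07 ± 0.12). Dnmt3l, the cofactor of new DNA methylation, lay at 3.43 ± 0.02 in E17.5 males and was not well above background in E17.5 females. Prm1, the sperm protamine, lay at 4.34 ± 0.06 in testis and was not well above background on any array outside testis and GS (-9.10 ± 0.20) except 1 of ES females.

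**Figure D1:**
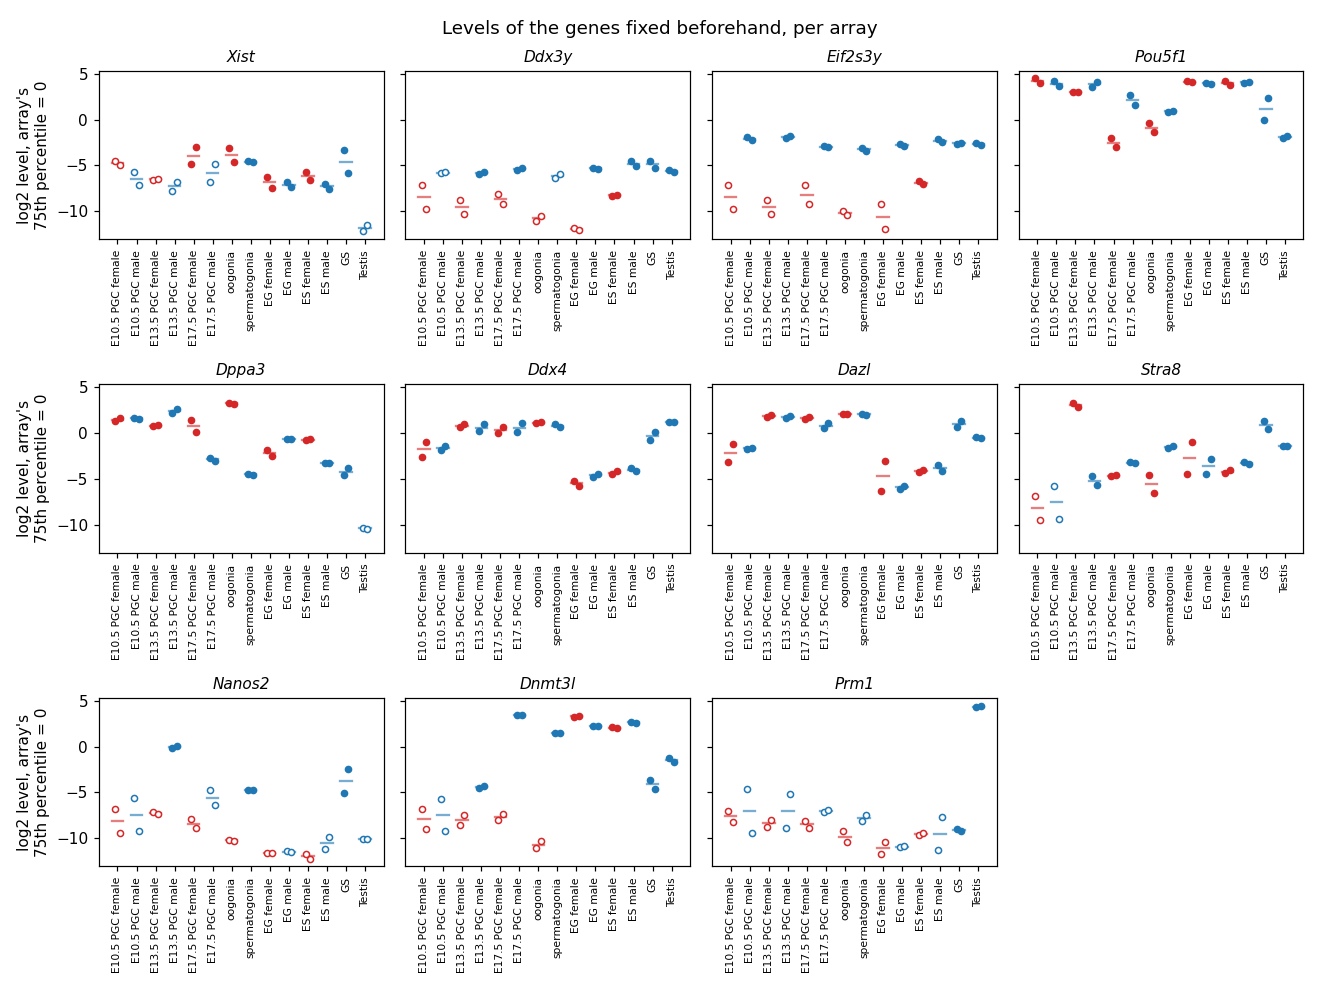
Level of 11 genes (log2 relative to each array's 75th percentile, vertical axis) on each of the 28 arrays, by group (horizontal axis). Circles are arrays, with replicate 1 to the left, red for female groups and oogonia and blue for the others, and bars are group means. Both circles of a group are hollow unless the gene was well above background on both arrays. Eif2s3y lies between -3.26 and -1.89 in male group means and between -10.60 and -6.91 in female ones, and Stra8 peaks in E13.5 females at 3.09.

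Between E10.5 and E13.5 PGC gained germ cell and meiotic transcripts and lost part of their pluripotency and Rhox transcripts (4 arrays against 4). Each stage is the mean of both sexes here. In the germ cell and genome defence list 15 of 19 genes rose and 0 fell (16 adjusted over the list alone), with a median change of 2.38 log2 units (camera adjusted p = 1.03e-07, or adjusted p = 0.132 with an estimated correlation). Tex101, a germ cell surface protein, rose by 4.22 ± 0.27 (log2, SE), Tdrd7, a germ granule protein, by 4.19 ± 0.22 and Mael, which acts in transposon silencing, by 3.79 ± 0.33. Of 14 meiotic prophase genes 12 rose and 1 fell (13 and 1 over the list alone), median 2.70, or 2.38 with dim members at their bounds (adjusted p = 2.08e-06, or adjusted p = 0.0985 with an estimated correlation). Stra8 was at least 27.2-fold higher (limma adjusted p = 1.27e-05). The synaptonemal complex gene Sycp1 rose by 5.05 ± 0.41 and the meiotic cohesin Rec8 by 3.77 ± 0.32, both well above background on 2 of 4 E10.5 arrays. Such means describe neither sex where the sexes differ. At E13.5 Stra8 lay at 3.09 in females and -5.21 in males, and Rec8 at -0.08 and -4.44. X-linked testis and multicopy genes rose in 10 of 12 cases (also over the list alone), median 1.66 and 1.53 at bounds (adjusted p = 0.0109, or adjusted p = 0.640 with an estimated correlation), among them the meiotic gene Tex11 (2.92 ± 0.28) and Taf7l, a germ cell transcription factor (at least 9.55-fold, adjusted p = 8.24e-05).

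Pluripotency genes fell in 7 of 18 cases and rose in 1 (same over the list alone), with a median of -0.77 (adjusted p = 1.76e-04, or adjusted p = 0.156 with an estimated correlation). Klf2 changed by -2.28 ± 0.32, Nanog by -2.14 ± 0.35, Esrrb by -1.94 ± 0.22, all of them transcription factors of naive pluripotency, and Tdh, the threonine dehydrogenase of pluripotent cells, by -1.70 ± 0.20. In the early germ cell specification list 4 of 11 genes fell and 1 rose (same over the list alone), median -0.67 (adjusted p = 0.00433, or adjusted p = 0.0613 with an estimated correlation). Tfap2c, a PGC specification factor, changed by -2.58 ± 0.34 and Kitl, the ligand of Kit, by 1.46 ± 0.49 (adjusted p = 0.0299), although with normexp background correction Kitl read -0.21. All 3 tested members of the X-linked Rhox homeobox cluster fell (also over the list alone), with a median of -2.31 (adjusted p = 3.72e-04, or adjusted p = 0.0613 with an estimated correlation), led by Rhox6 at -2.86 ± 0.23. Outside the lists, Cited1 and Sp5, both transcriptional regulators, were at least 24.5-fold and 14.5-fold higher. The amino acid transporters Slc7a3 (-4.72 ± 0.29) and Slc1a3 (-4.64 ± 0.54), the kinase Lck (-4.31 ± 0.30) and the nucleosome binder Hmgn5 (-4.19 ± 0.30) fell. Slc7a3 was well above background on only 1 of 4 E13.5 arrays.

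In all, limma called 4075 of 11645 genes between these stages, 2711 higher and 1364 lower at E13.5. A slide block left 839 (607 higher, 232 lower) and a scan-day block 4826 (3246 higher, 1580 lower). The split depended on the scaling, with 2191 higher and 1725 lower after quantile normalization, 1369 and 2239 with the percentile over all probes, 433 and 1074 with normexp and 915 and 175 with the deposited values. List medians on days 1 and 2 were 2.41 and 2.26 for germ cell genes, 2.22 and 2.86 for meiotic genes, -0.83 and -0.62 for pluripotency genes, -0.72 and -0.55 for early germ cell genes, 1.72 and 1.72 for X-linked testis genes and -2.21 and -2.41 for Rhox. With scan day as a block the adjusted p of these lists lay between 5.75e-07 and 0.0286.

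From E13.5 to E17.5 pluripotency, early germ cell, Rhox and cell cycle transcripts fell in PGC, again as means of both sexes (4 arrays against 4). Of 19 pluripotency genes 13 fell and 2 rose (14 and 2 over the list alone), median -3.24 (adjusted p = 4.89e-10, and adjusted p = 0.0209 with an estimated correlation). Tdh changed by -5.84 ± 0.20, Sox2 by -5.72 ± 0.83, Nanog by -5.12 ± 0.35 and Dppa2, a chromatin factor of pluripotent cells, by -4.40 ± 0.43. Sox2 and Nanog were each well above background on 2 of 4 E17.5 arrays and Dppa2 on 1, so their sizes rest partly on dim values. Early germ cell genes fell in 9 of 11 cases and rose in 1 (same over the list alone), median -2.64 (adjusted p = 3.68e-08, and adjusted p = 5.86e-04 with an estimated correlation). Ifitm1, an interferon-inducible membrane protein, changed by -4.96 ± 0.28, and the PGC specification factors Prdm14, Tfap2c and Prdm1 by -4.41 ± 0.39, -4.10 ± 0.34 and -3.69 ± 0.38. The 3 Rhox genes fell (also over the list alone), median -3.33 (adjusted p = 2.42e-05, and adjusted p = 0.0209 with an estimated correlation). Proliferation genes fell in 16 of 20 cases (17 over the list alone), median -1.44 (adjusted p = 4.38e-11, or adjusted p = 0.125 with an estimated correlation). The mitotic cyclin Ccnb1 changed by -2.58 ± 0.25, the replicative helicase subunit Mcm7 by -2.29 ± 0.19 and topoisomerase Top2a by -2.21 ± 0.44. Histone repressive mark genes fell in 5 of 11 cases and rose in 1 (same over the list alone), median -0.40 (adjusted p = 0.0483, or adjusted p = 0.505 with an estimated correlation and 0.0685 with a scan-day block). The Polycomb subunits Ezh2 and Suz12 changed by -1.02 ± 0.21 and -0.91 ± 0.21.

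Spermatocyte and spermatid genes rose in 12 of 15 cases and fell in 0 (13 over the list alone), median 1.78 and 1.54 at bounds (adjusted p = 2.50e-04, or adjusted p = 0.471 with an estimated correlation). Piwil1, a piRNA-binding protein, rose by 3.24 ± 0.37 and the sperm anchoring protein Akap3 was at least 5.07-fold higher (adjusted p = 8.40e-04). All 4 tested blood and endothelium genes rose too (also over the list alone), median 3.70 (adjusted p = 0.0483, or adjusted p = 0.471 with an estimated correlation). Alas2, the erythroid haem enzyme, rose by 5.01 ± 1.03 and the alpha globin Hba-a1 by 4.30 ± 1.36. The oocyte genes Zp2, of the egg coat, and Nlrp4f were at least 17.1-fold and 17.8-fold higher. Morn5 (6.40 ± 0.72), Sdcbp2 (6.02 ± 0.61) and the transcription factor Prdm16 (5.99 ± 0.64) rose. In total 5943 of 13983 genes changed, 3864 higher and 2079 lower. A slide block left 1755 (1223 higher, 532 lower) and a scan-day block 6731 (4299 higher, 2432 lower). Quantile normalization gave 2905 higher and 2599 lower, and the percentile over all probes 2229 and 3207. Medians on days 1 and 2 were -3.01 and -2.71 for pluripotency, -2.13 and -2.60 for early germ cell, -1.39 and -1.47 for proliferation, -3.34 and -3.31 for Rhox, 1.92 and 1.98 for spermatocyte, -0.41 and -0.39 for histone and 3.40 and 3.99 for blood genes.

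**Figure D2:**
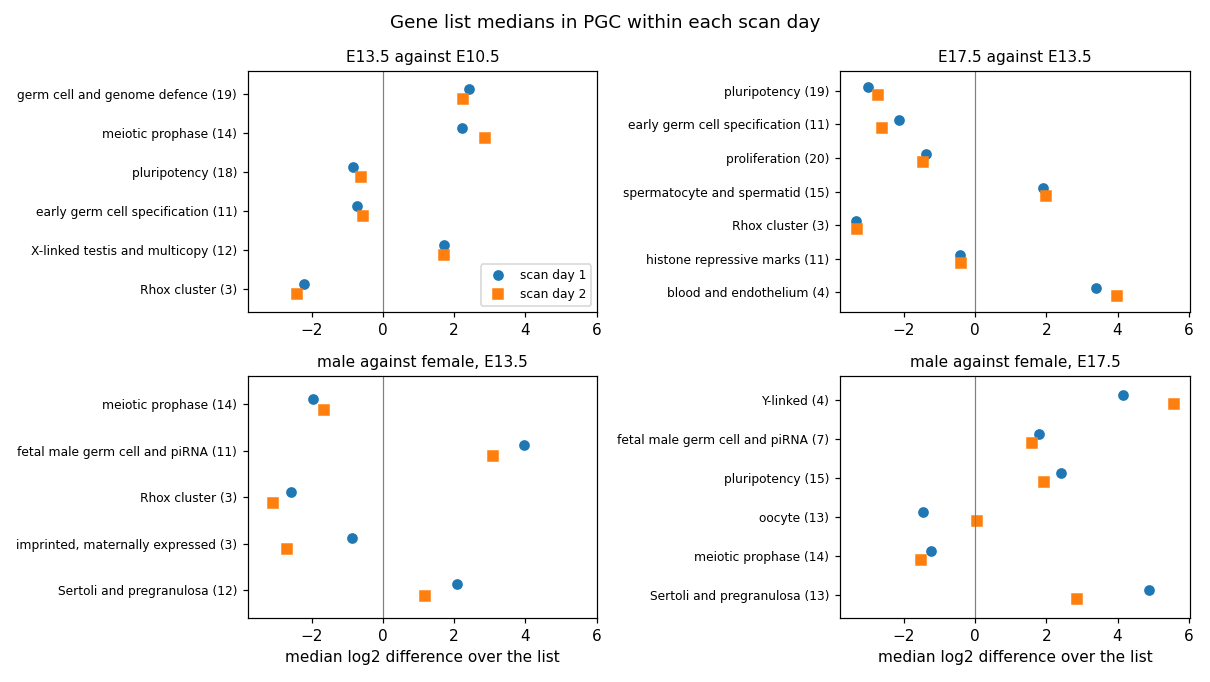
Median log2 fold change of each described gene list (horizontal axis, log2) in the PGC comparisons, computed separately from the arrays of scan day 1 and of scan day 2. For E17.5 against E13.5 the pluripotency list lies at -3.01 and -2.71, and in E17.5 males against females the Sertoli list lies at 4.87 and 2.85.

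At E10.5 male and female PGC (2 arrays each) differed in 1 of 7513 tested genes, Eif2s3y, which was at least 18.1-fold higher in males (limma adjusted p = 0.0094). It was also the 1 Y-linked list gene that could be tested, and it lay higher in males by 5.17 on scan day 1 and 7.58 on day 2. Without adjustment, 124 genes fell under 0.05. The slide block called 0 of these genes by limma (44 without adjustment), the scan-day block called 1, and 0 (74) were called without E10.5 male replicate 1. Without male replicate 2, female replicate 2 and female replicate 1 the counts were 43, 13 and 3, and with a common floor 16. X escape genes, which are transcribed from both X chromosomes, and Xist were lower in males as a list, median -0.74 (camera adjusted p = 6.55e-06, or adjusted p = 0.0525 with an estimated correlation; day medians -0.77 and -0.58), although 0 of 4 members passed by limma (1 over the list alone). The largest, the histone demethylase Kdm6a, read -1.13 ± 0.39 (adjusted p = 0.999). Fetal male germ cell and piRNA genes read higher, median 0.56 (adjusted p = 0.0191, or adjusted p = 0.0644 with an estimated correlation and 0.0590 with a scan-day block; day medians 0.82 and 0.19). Of the 5 members 0 passed by limma (1 over the list alone), and the largest, the DNA methyltransferase Dnmt3a, read 1.14 ± 0.37 (adjusted p = 0.999).

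At E13.5 the sexes had parted (2 arrays each). Of 11 fetal male germ cell genes 6 were higher in males and 0 lower (7 over the list alone), median 3.53 (adjusted p = 2.99e-05, and adjusted p = 0.00467 with an estimated correlation). The Nodal antagonist Lefty2 was at least 138-fold higher (adjusted p = 3.65e-06), Lefty1 differed by 7.42 ± 0.57 and Nanos2 by 7.15 ± 1.02. Both Lefty genes lie on chromosome 1. Meiotic prophase genes were lower in males in 8 of 14 cases (10 over the list alone), median -1.84 (adjusted p = 3.18e-06, or adjusted p = 0.0934 with an estimated correlation), with Stra8 at -8.31 ± 1.14, Rec8 at -4.36 ± 0.45, the recombinase Dmc1 at -3.62 ± 0.47 and the axial element gene Sycp3 at -2.40 ± 0.44. Rhox6 (-2.90 ± 0.32) and Rhox9 (-2.89 ± 0.33) were lower in males, 2 of 3 in the list and over the list alone (median -2.89, adjusted p = 0.0020, or adjusted p = 0.0934 with an estimated correlation). Maternally expressed imprinted genes were lower in 1 of 3 cases (2 over the list alone), median -1.61 (adjusted p = 0.0164, or adjusted p = 0.102 with an estimated correlation), with Phlda2 at least 45.2-fold lower (adjusted p = 4.51e-06). The transcription factor Gata2 differed by -5.70 ± 0.58 and Dmrtc2 by -6.24 ± 0.50, and Prom1 was at least 20.4-fold lower.

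Genes of testis supporting (Sertoli) cells moved with sex as well. In the Sertoli and pregranulosa list 6 of 12 genes were higher in males and 1 lower (same over the list alone), median 1.68 (adjusted p = 0.0116, or adjusted p = 0.222 with an estimated correlation). The prostaglandin synthase Ptgds was at least 36.3-fold higher. The Sertoli cell transcription factor Sox9 differed by 4.87 ± 0.66 and clusterin (Clu) by 3.87 ± 0.69, and Irx3, a pregranulosa gene, was at least 2.78-fold lower. Cst9, a cystatin gene, was at least 77.9-fold higher. In all 1644 of 11553 genes differed, 633 higher and 1011 lower in males. With only these groups in the fit limma called 0 (1502 without adjustment). The slide block, fitted on the PGC arrays alone, left 30 (16 higher, 14 lower), and the scan-day block 2148 (856 higher, 1292 lower). Both sexes lay on the same slides, so the slide block changes the estimated spread and not the sex difference. Slide as a random block gave 2848. Normexp gave 208 higher and 120 lower, and the deposited values 88 and 1061. Day 1 and day 2 medians were 3.97 and 3.08 for fetal male genes, -1.95 and -1.66 for meiotic genes, -2.58 and -3.08 for Rhox, -0.86 and -2.68 for imprinted genes and 2.07 and 1.18 for Sertoli genes.

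At E17.5 males differed from females in 6920 of 13385 genes, 4114 higher and 2806 lower (2 arrays each). Dnmt3l was at least 953-fold higher in males (limma adjusted p = 5.83e-08), the chromatin gene Morc1, which silences transposons, differed by 4.16 ± 0.52 and Dnmt3a by 1.70 ± 0.37. In the fetal male list 4 of 7 genes were higher and 2 lower (same over the list alone), median 1.70, and the list did not pass (adjusted p = 0.390). Pluripotency genes were higher in males in 9 of 15 cases and lower in 1 (same over the list alone), median 1.92 and 1.67 at bounds, again short of the threshold (adjusted p = 0.0557). The stem cell chromatin factor Utf1 was at least 81.4-fold higher, Pou5f1 differed by 4.65 ± 0.58 and Esrrb by 4.23 ± 0.30. Meiotic genes were lower in males in 7 of 14 cases and higher in 1, Rec8 (4.41 ± 0.45), with a median of -1.26 (adjusted p = 0.0588, same counts over the list alone). Sycp1 differed by -4.83 ± 0.58, Sycp3 by -4.06 ± 0.44 and the cohesin Smc1b by -3.42 ± 0.61. Oocyte genes split into 5 lower and 3 higher of 13 (same over the list alone), median -0.63 (adjusted p = 0.416). The oocyte transcription factors Figla (-5.67 ± 1.02), Lhx8 (-5.66 ± 1.11) and Nobox (-4.29 ± 0.89) were lower in males, while Zar1 was at least 4.02-fold higher. The BMP target Id1 differed by -5.84 ± 0.65. All 4 tested Y-linked genes were higher (also over the list alone), median 4.87 and 2.91 at bounds (adjusted p = 0.0557), with the RNA-binding gene Rbmy at least 46.8-fold higher.

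Sertoli and pregranulosa genes were higher in E17.5 males in 10 of 13 cases and lower in 0 (same over the list alone), median 4.17 and 3.32 at bounds (adjusted p = 0.0160, or adjusted p = 0.561 with an estimated correlation). Ptgds differed by 6.69 ± 1.02, Sox9 was at least 38.6-fold higher, and Dhh, a hedgehog ligand of Sertoli cells, at least 8.37-fold. Afp, Cst9 and Cdhr1 were at least 216-fold, 132-fold and 84.4-fold higher. The slide block left 6003 (3676 higher, 2327 lower) and the scan-day block 7612 (4495 higher, 3117 lower), while the percentile over all probes gave 3206 higher and 3579 lower and the deposited values 1850 and 2077. Day medians were 1.79 and 1.60 for fetal male, 2.41 and 1.94 for pluripotency, -1.25 and -1.53 for meiotic, -1.46 and 0.05 for oocyte, 4.16 and 5.58 for Y-linked and 4.87 and 2.85 for Sertoli genes.

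The sex difference itself changed with stage. Between E10.5 and E13.5 it changed in 444 of 11645 genes, towards males in 139 and towards females in 305. Fetal male genes moved towards males in 4 of 11 cases (6 and 1 the other way over the list alone), median 3.10 (adjusted p = 4.90e-04, and adjusted p = 0.0158 with an estimated correlation; day medians 2.63 and 3.10). Meiotic genes moved towards females in 5 of 14 (6 over the list alone), median -1.93 and -1.71 at bounds (adjusted p = 5.86e-06, or adjusted p = 0.0993 with an estimated correlation; day medians -2.40 and -1.53). Lefty1 moved by 6.86 ± 0.81 and Rec8 by -4.78 ± 0.64. The slide block called 0 by limma (1848 without adjustment) and the scan-day block 747 (248 and 499). Leaving out 1 array gave 146 (E13.5 female replicate 1) to 920 (E10.5 male replicate 2), and the percentile over all probes gave 125 towards males and 162 towards females, normexp 7 and 8. From E13.5 to E17.5 the difference changed in 4096 of 13983 genes, 2493 towards males and 1603 towards females (slide block 2330, with 1615 and 715; scan-day block 4875, with 2883 and 1992). The percentile over all probes gave 1880 and 2140, and the deposited values 1421 and 199. All 3 Rhox genes moved towards males (also over the list alone), median 3.34 (adjusted p = 0.0608, or 0.0489 with a scan-day block; day medians 3.30 and 3.39). Of 3 maternally expressed imprinted genes 2 did (same over the list alone), median 5.10 and 0.89 at bounds (adjusted p = 0.0695; day medians 4.32 and 5.88), with the growth factor receptor adaptor Grb10 at 5.10 ± 0.94. Phlda2 was the other, with no exact size, since it was not well above background in E13.5 males and E17.5 females.

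X-linked genes as a class read lower in males than in females in PGC at all 3 stages and in EG and ES cells, by camera with its preset correlation but not with an estimated one. Against autosomal genes the X-linked shift, male minus female, was -0.11 log2 units at E10.5 (121 genes), -0.62 at E13.5 (170) and -0.62 at E17.5 (198), -0.47 in EG cells (304) and -0.71 in ES cells (275), where a single dose against a double dose of every X-linked gene would be 1 unit. At E13.5 81.2% of X-linked genes were lower in males against 50.5% of autosomal genes. The shares were 59.5% against 42.8% at E10.5, 66.7% against 50.7% at E17.5, 80.3% against 52.5% in EG and 82.9% against 49.3% in ES cells. At E17.5 32 of these X-linked genes were called higher and 79 lower in males, so the shift was less uniform there. The camera adjusted p were 3.81e-08, 1.38e-11, 0.00121, 1.63e-10 and 5.61e-16 in that order. With an estimated correlation they were adjusted p = 0.115, 0.0912, 0.346, 0.0912 and 0.0743. The shift moved by -0.49 between E10.5 and E13.5 (116 genes, adjusted p = 2.56e-07, or adjusted p = 0.208 with an estimated correlation) and by 0.11 from E13.5 to E17.5 (158 genes, adjusted p = 0.658). Within scan days 1 and 2 it read -0.07 and -0.15 at E10.5, -0.64 and -0.66 at E13.5, and -0.57 and -0.66 at E17.5. In EG cells it was -0.13 against female replicate 1 alone and -0.81 against replicate 2 alone.

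**Figure D3:**
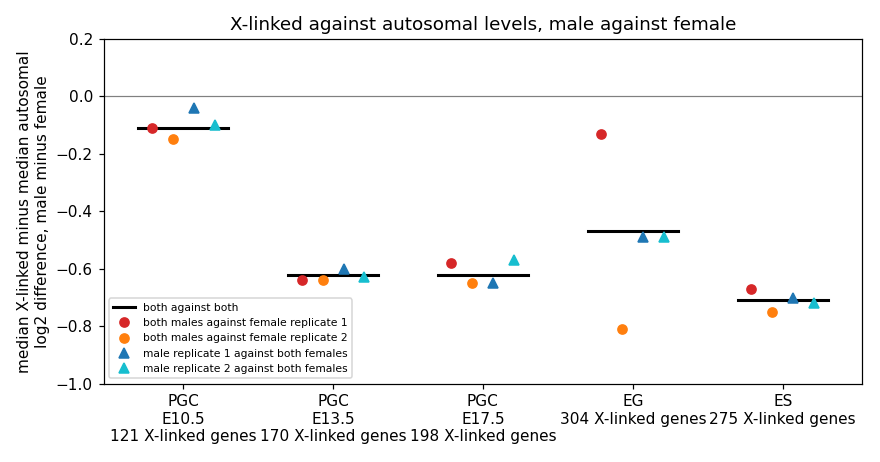
X-linked minus autosomal median log2 difference between males and females (vertical axis, log2 units) in PGC at 3 stages, EG cells and ES cells. Bars give both males against both females, circles both males against 1 female replicate, and triangles 1 male replicate against both females. The E13.5 and E17.5 PGC bars are both at -0.62. In EG cells the circles lie apart at -0.13 (female replicate 1) and -0.81 (female replicate 2), and both triangles lie at -0.49.

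Spermatogonia and oogonia (2 arrays each) differed in 7582 of 15439 genes, 4964 higher and 2618 lower in spermatogonia. Oocyte genes were lower in 11 of 16 cases and higher in 1 (same over the list alone), median -3.22 and -2.98 at bounds (adjusted p = 1.88e-04, or adjusted p = 0.424 with an estimated correlation). Figla differed by -8.08 ± 1.02, Nobox by -5.52 ± 0.89, and Padi6, a maternal lattice protein, was at least 46.2-fold lower (limma adjusted p = 1.26e-04). Dppa3 differed by -7.77 ± 0.35 and Trp63, which guards oocyte genome integrity, by -6.51 ± 0.70. Spermatogonial genes were higher in 11 of 16 cases and lower in 2 (12 and 2 over the list alone), median 2.48 and 2.07 at bounds (adjusted p = 0.0167, or adjusted p = 0.424 with an estimated correlation), led by the adhesion molecule Mcam (7.31 ± 0.45) and Tspan8, a surface marker of stem spermatogonia (7.27 ± 0.83). Pluripotency genes were higher in 10 of 17 (11 over the list alone), median 1.97 (adjusted p = 0.0455, or adjusted p = 0.424 with an estimated correlation), with Utf1 at least 84.5-fold higher and Dppa4 at 4.49 ± 0.42. Proliferation genes were lower in 10 of 20 and higher in 2 (same over the list alone), median -1.09 (adjusted p = 0.00575, or adjusted p = 0.468 with an estimated correlation), with survivin (Birc5) at -4.43 ± 0.26 and the cyclin Ccnb2 at -4.83 ± 0.39. Of 9 fetal male genes 6 were higher and 2 lower (same over the list alone), median 4.42 and 3.76 at bounds (adjusted p = 0.180), with Dnmt3l at least 1049-fold higher. All 4 Y-linked genes were higher (also over the list alone), median 8.05 and 6.07 at bounds (adjusted p = 0.0167, or adjusted p = 0.424 with an estimated correlation), and 3 of 5 X escape genes lower (same over the list alone), median -1.16 (adjusted p = 0.0530), with Eif2s3x at -2.30 ± 0.34. Afp, an alpha-fetoprotein, differed by 9.86 ± 1.19 and the tight junction gene Cldn18 was at least 166-fold higher. Somatic genes differed too, with Dcn at -0.67 and -0.86 in spermatogonia and -2.24 and -5.13 in oogonia, Clu at -1.73 and -1.82 against -4.16 and -4.17, and the mast cell gene Cma1 well above background in oogonia alone (-3.36 and -0.21). Each group lay on 1 slide of its own, so slide and group cannot be told apart, and slide as a random block left 3669. Splits were 3385 higher and 3601 lower with quantile normalization, 4776 and 1330 with normexp, 3280 and 4413 with all probes and 1804 and 4030 with the deposited values.

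Against E17.5 male PGC, spermatogonia held less cell cycle RNA and more of some stem cell regulators (2 arrays each). Proliferation genes were lower in 12 of 20 (16 over the list alone), median -1.23 (adjusted p = 7.80e-07, or adjusted p = 0.480 with an estimated correlation), with Top2a at -3.33 ± 0.62 and the mitotic kinase Cdk1 at -2.73 ± 0.49. Spermatogonial genes were higher in 4 of 16 (same over the list alone), median 0.60 and 0.40 at bounds (adjusted p = 0.0171, or adjusted p = 0.480 with an estimated correlation), with the stem cell gene Id4 at 3.84 ± 0.28, the POU factor Pou3f1 at 3.22 ± 0.40 and Foxo1 at 0.78 ± 0.24. Sertoli genes were lower in 8 of 13 (same over the list alone), median -2.16 (adjusted p = 0.0126, or adjusted p = 0.480 with an estimated correlation), with Ptgds at -3.30 ± 1.02 and Clu at -2.90 ± 0.69. Immediate early and heat shock genes, which respond to handling stress, were higher in 2 of 9 (4 over the list alone), median 0.98 (adjusted p = 0.0171, or adjusted p = 0.933 with an estimated correlation), with Egr1 at 3.50 ± 0.71 and Ier2 at 1.21 ± 0.34. The neutrophil protein S100a9 was at least 11.6-fold lower (adjusted p = 0.0113) and Fam81a at least 4.79-fold higher. Among markers of other cells, Dcn lay at -0.67 and -0.86 in spermatogonia and at -2.27 and -2.48 in E17.5 males, while Col1a1 overlapped. The mast cell gene Cma1 was well above background on both E17.5 male arrays (-4.85 and -4.31) and on neither spermatogonia array. Overall limma called 2138 of 13745 genes, 913 higher and 1225 lower. Slide and group cannot be told apart here. Slide as a random block left 165, only these 2 groups in the fit left 0 (4493 without adjustment), and omitting spermatogonia replicate 1 left 401. Splits were 1380 higher and 964 lower with quantile normalization, 180 and 379 with normexp, 1230 and 675 with all probes and 99 and 83 with the deposited values.

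Oogonia held more oocyte RNA than E17.5 female PGC (2 arrays each). Oocyte genes were higher in 6 of 15 cases and lower in 0 (8 over the list alone), median 2.72 (adjusted p = 2.76e-06, or adjusted p = 0.618 with an estimated correlation). The maternal-effect gene Nlrp14 differed by 5.08 ± 0.60, the egg coat genes Zp1 and Zp3 by 3.48 ± 0.96 and 3.45 ± 0.66, and Khdc3, of the subcortical maternal complex, was at least 6.77-fold higher (adjusted p = 8.54e-04). Meiotic genes were lower in 5 of 14 (6 over the list alone), median -1.05, short of the threshold as a list (adjusted p = 0.133), with Dmc1 at -2.75 ± 0.47 and Spo11, which makes meiotic DNA breaks, at -1.50 ± 0.41. Of 2 tested blood genes 1 was lower (same over the list alone, median -3.98), Alas2 at -4.73 ± 1.46, too few for a list test. Oas1c and Dhrs2 were at least 13.1-fold and 9.95-fold higher, and Lurap1l differed by 3.97 ± 0.72. In total 2713 of 14007 genes differed, 847 higher and 1866 lower. Slide and group cannot be told apart. Slide as a random block left 423, only these groups in the fit 0 (3870 without adjustment by limma), and omitting oogonia replicate 1 left 763. Splits were 1229 higher and 588 lower with quantile normalization, 363 and 2005 with normexp, 1975 and 434 with all probes and 235 and 15 with the deposited values.

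EG cells (4 arrays) carried more pluripotency RNA and less germ cell and meiotic RNA than PGC of E10.5 and E13.5 (8 arrays). Pluripotency genes were higher in 13 of 22 cases and lower in 1 (16 and 1 over the list alone), median 1.22 (adjusted p = 1.10e-05, or adjusted p = 0.123 with an estimated correlation). The self-renewal factors Tbx3, Nr0b1 and Klf4 differed by 7.07 ± 0.79, 5.61 ± 0.55 and 4.94 ± 0.33, with 2, 2 and 5 of 8 PGC arrays well above background. Germ cell genes were lower in 15 of 19 and higher in 1 (16 and 1 over the list alone), median -3.0 (adjusted p = 2.69e-08, or adjusted p = 0.126 with an estimated correlation), with Fkbp6 at -5.35 ± 0.33 and Dazl at -5.25 ± 0.44. Meiotic genes were lower in 12 of 15 and higher in 1 (same over the list alone), median -2.86 (adjusted p = 1.02e-05, or adjusted p = 0.123 with an estimated correlation), with Tex12 at -5.21 ± 0.26 and Spo11 at -4.79 ± 0.25. Early germ cell genes were lower in 8 of 11 (9 over the list alone), median -1.24 (adjusted p = 0.00398, or adjusted p = 0.0723 with an estimated correlation), with the RNA-binding gene Dnd1 at -4.29 ± 0.21, the receptor Kit at -3.12 ± 0.19 and Dppa3 at -2.96 ± 0.22. All 3 Rhox genes were lower (also over the list alone), median -2.72 (adjusted p = 0.00483, or adjusted p = 0.123 with an estimated correlation). In the DNA methylation machinery 5 of 16 genes were higher and 4 lower (same over the list alone). Its median was -0.19, its mean 1.14, and camera's direction was up (adjusted p = 0.271). The higher members were led by Dnmt3l (9.73 ± 0.50, with 3 of 8 PGC arrays well above background), the methyltransferase Dnmt3b (5.25 ± 0.19) and Uhrf1, which guides maintenance methylation (2.10 ± 0.24).

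Outside these lists the ES cell Ras gene Eras differed by 7.17 ± 0.65 and the nucleoside enzyme Upp1 by 6.74 ± 0.31, and the tight junction gene Cldn4 was at least 24.3-fold higher. Khdc1a was at least 83.0-fold lower, and Isl2 (-6.65 ± 0.23), Rnf182 (-5.93 ± 0.23) and Rab6b (-4.61 ± 0.15) were lower. In all 7947 of 18188 genes differed, 3574 higher and 4373 lower, 803 of the latter without order because no PGC group measured them fully. Slide, day and group cannot be told apart, and more probes were well above background on each EG array (25414 to 25831) than on any of these PGC arrays (7785 to 20447). Slide as a random block left 1836, a common floor 4300. The split was 5537 higher and 2821 lower with quantile normalization, 1340 and 13615 with normexp and 5553 and 997 with the deposited values.

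EG and ES cells (4 arrays each) had like levels of the pluripotency list, with 0 of 22 genes called by limma (also 0 over the list alone), a median of 0.14 and camera adjusted p = 0.890. The largest difference there was L1td1, an RNA-binding gene, at -1.03 ± 0.73. Early germ cell genes were higher in EG in 2 of 11 (3 over the list alone), median 0.62 (adjusted p = 0.00668, or adjusted p = 0.0978 with an estimated correlation), the RNA-binding Nanos3 at 1.95 ± 0.35 and Ifitm1 at 1.63 ± 0.28. Germ cell genes were lower in 6 of 19 (12 over the list alone), median -0.88 (adjusted p = 1.63e-07, or adjusted p = 0.209 with an estimated correlation), with Fkbp6 at -1.74 ± 0.38 and the meiotic gene Hormad1 at -1.69 ± 0.44. X-linked testis genes were lower in 4 of 18 (6, and 3 higher, over the list alone), median -1.27 and -0.60 at bounds (adjusted p = 0.00319, or adjusted p = 0.569 with an estimated correlation), with the cancer-testis gene Magea4 at -3.27 ± 0.62. The 2 EG female arrays differed on both lists, replicate 1 minus replicate 2, by -1.05 for germ cell genes and -3.45 for X-linked testis genes. The neuropeptide gene Npy differed by 3.76 ± 0.52, the stem cell ubiquitin ligase Trim71 by -3.09 ± 0.32 and the neural factor Zic2 by -2.88 ± 0.62. In all 1211 of 19091 genes differed, 831 higher and 380 lower in EG. Slide, strain and cell type cannot be told apart here. Slide as a random block left 0 (limma, 399 without adjustment), omitting ES male replicate 1 left 414, only these groups in the fit gave 4046, and the deposited values gave 406 higher and 400 lower.

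Male and female EG cells (2 arrays each, on 1 slide, so a slide block gives no value) differed in 180 of 18034 genes, 97 higher and 83 lower in males. Y-linked genes were higher in 2 of 3 (same over the list alone), median 6.60 and 4.33 at bounds (adjusted p = 1.19e-06, or adjusted p = 0.0730 with an estimated correlation), Eif2s3y by 7.82 ± 0.85. X-linked testis genes were lower in 3 of 13 (6 over the list alone), median -1.80 (adjusted p = 2.18e-07, or adjusted p = 0.246 with an estimated correlation), with Xlr5c at -4.27 ± 0.82 and the ferritin-like Fthl17e at -3.69 ± 0.76. This rested on female replicate 2, since the median of the 10 members well above background on all 4 arrays was -0.09 against replicate 1 and -3.36 against replicate 2. Mesenchyme and fibroblast genes read higher as a list, median 3.0 (adjusted p = 1.33e-06, or adjusted p = 0.246 with an estimated correlation). Of its 12 members 0 passed by limma (7 over the list alone), and the collagen Col3a1 read 4.57 ± 1.60. The matrix protein Mgp differed by 6.40 ± 0.74, the calcium-binding S100g by 6.72 ± 1.37 and the Nodal antagonist Cer1 was at least 18.9-fold higher. The 2 female arrays differed in the fibroblast and macrophage genes Dcn (-3.58 and -11.54) and Lyz2 (-3.06 and -11.70). Leaving out 1 array gave between 14 (EG male replicate 1) and 419 (EG female replicate 1) called genes, and only these groups in the fit 0 (limma, 3620 without adjustment).

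Male and female ES cells (2 arrays each, on 1 slide, so a slide block gives no value) were lines of different strains and differed in 706 of 17846 genes, 292 higher and 414 lower in males. Rhox genes were lower in males in 2 of 3 (same over the list alone), median -3.48 (adjusted p = 3.47e-06, and adjusted p = 0.0178 with an estimated correlation), with Rhox6 at -4.11 ± 0.32. Early germ cell genes were lower in 4 of 11 (same over the list alone), median -0.96 (adjusted p = 0.00475, and adjusted p = 0.0400 with an estimated correlation), with Prdm14 at -2.72 ± 0.55, Dppa3 at -2.54 ± 0.35 and Kit at -1.90 ± 0.31. Y-linked genes were higher in 2 of 3 (same over the list alone), median 3.48 (adjusted p = 9.64e-04, or adjusted p = 0.156 with an estimated correlation). Mesenchyme genes read lower, median -2.79 (adjusted p = 0.00108, or adjusted p = 0.529 with an estimated correlation), with 0 of 13 passing by limma (also 0 over the list alone) and lumican (Lum) at -3.69 ± 1.97. The serotonin receptor Htr5a was at least 53.2-fold higher in males and the ubiquitin-like Ubd at least 55.0-fold lower. The regenerating-islet gene Reg2, the serpin Serpina3m and Smcr8 were at least 30.8-fold, 25.5-fold and 20.6-fold lower. Leaving out 1 array gave 133 (ES male replicate 1) to 201 called genes, and trend with robust eBayes 1130.

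GS cells held more cell cycle and stress-response RNA than spermatogonia and less Rhox RNA (2 arrays each). Proliferation genes were higher in 14 of 20 (17 over the list alone), median 1.71 (adjusted p = 1.33e-09, or adjusted p = 0.326 with an estimated correlation), with Top2a at 3.97 ± 0.62 and Cdk1 at 2.94 ± 0.49. All 3 Rhox genes were lower (also over the list alone), median -5.35 (adjusted p = 1.53e-06, and adjusted p = 0.0172 with an estimated correlation). Immediate early genes were higher in 6 of 12 (7 over the list alone), median 1.71 and 1.59 at bounds (adjusted p = 0.00110, or adjusted p = 0.464 with an estimated correlation), with Klf6 at 3.13 ± 0.77, Dusp1 at 2.19 ± 0.63 and Junb at least 3.25-fold higher, although Junb read -0.52 with normexp. This list was higher on GS replicate 1 than on replicate 2 by a median of 1.64 (11 of 12). Blood and endothelium genes were lower in 6 of 7 (same over the list alone), median -4.34 (adjusted p = 6.64e-04, or adjusted p = 0.326 with an estimated correlation), Hba-a1 by -8.71 ± 1.92 and the endothelial receptor Tie1 by -5.66 ± 0.77. Spermatogonial genes were lower in 5 of 20 and higher in 0 (5 and 2 over the list alone), median -0.63, and did not pass as a list (adjusted p = 0.204), with Tspan8 at -6.02 ± 0.83 and Foxo1 at -1.29 ± 0.24. Mesenchyme genes were higher in 2 of 13 (0 over the list alone), median 1.96 and 1.60 at bounds (adjusted p = 0.1005), the collagen cross-linker Lox at 4.06 ± 1.39. The matrix protease Mmp3 and the chemokines Ccl2, Ccl7 and Cxcl1 were at least 236-fold, 289-fold, 147-fold and 136-fold higher, with Mmp3 at 2.86 and -0.71 on the 2 GS arrays. Krt84 and Cst9 were at least 185-fold and 196-fold lower. In all 5387 of 21225 genes differed, 2663 higher and 2724 lower. Slide and group cannot be told apart, and slide as a random block left 868. Omitting spermatogonia replicate 1 left 2759, and normexp gave 1295 higher and 12301 lower.

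Against adult testis, on the same slide, so that a slide block gives no value, GS cells held far less RNA of later sperm stages (2 arrays each). All 30 spermatocyte and spermatid genes were lower (also over the list alone), median -11.16 and -10.96 at bounds (adjusted p = 4.59e-20, or adjusted p = 0.115 with an estimated correlation). The sperm genes Gapdhs, Ropn1 and Smcp were at least 11470-fold, 8182-fold and 7491-fold lower and Prm1 differed by -13.44 ± 1.34. All 6 Leydig and steroidogenic genes were lower (also over the list alone), median -7.83 and -7.09 at bounds (adjusted p = 0.00220, or adjusted p = 0.308 with an estimated correlation), with the steroid enzymes Hsd3b1 at -8.64 ± 1.20 and Cyp11a1 at -8.06 ± 1.01. Early germ cell genes were higher in 8 of 11 (same over the list alone), median 2.60 (adjusted p = 1.08e-04, and adjusted p = 0.0117 with an estimated correlation), with Dppa3 at least 59.5-fold higher and Prdm1 at 5.39 ± 0.54. Spermatogonial genes were higher in 13 of 20 and lower in 2 (15 and 2 over the list alone), median 2.63 and 2.50 at bounds (adjusted p = 2.26e-05, and adjusted p = 0.0358 with an estimated correlation), with Pou3f1 at 5.52 ± 0.40 and the cyclin Ccnd2 at 4.55 ± 0.50. Paternally expressed imprinted genes were higher in 9 of 14 and lower in 1 (same over the list alone), median 2.92 and 2.76 at bounds (adjusted p = 0.00244, or 0.136 with an estimated correlation), with Ndn at 3.94 ± 0.65, the growth regulator Dlk1 at 3.61 ± 0.59 and Rasgrf1 at least 10.7-fold lower. GS replicate 1 exceeded replicate 2 there by a median of 1.26 (7 of 13). Hox genes were higher in 15 of 31 and lower in 2 (17 and 3 over the list alone), median 2.26 and 1.80 at bounds (adjusted p = 0.00995, or adjusted p = 0.602 with an estimated correlation), with Hoxb7 at 7.04 ± 0.99 and Hoxa4 at -6.84 ± 0.98.

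Mesenchyme genes were also higher in GS cells than in testis, 6 of 13 (same over the list alone), median 3.78 (adjusted p = 0.00625, or adjusted p = 0.506 with an estimated correlation), with Lox at 8.36 ± 1.39 and Col1a1 at 4.14 ± 1.06. The 2 GS arrays differed in these genes, with Dcn at 2.71 and -2.82. The BMP antagonist Grem1 and the prostaglandin synthase Ptgs2 were at least 577-fold and 302-fold higher, and Mmp3 at least 2343-fold. Of 24177 genes 11278 differed, 5155 higher and 6123 lower. Quantile normalization gave 6212 higher and 4471 lower, all probes 6715 and 4960, and the deposited values 6236 and 4471. Over all comparisons the median of all tested genes lay within 0.33 log2 units of 0, and the other scalings moved it by -1.49 to 0.81. Changes were not centred on that median, so the directions above depend on the scaling of each array.

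**Figure D4:**
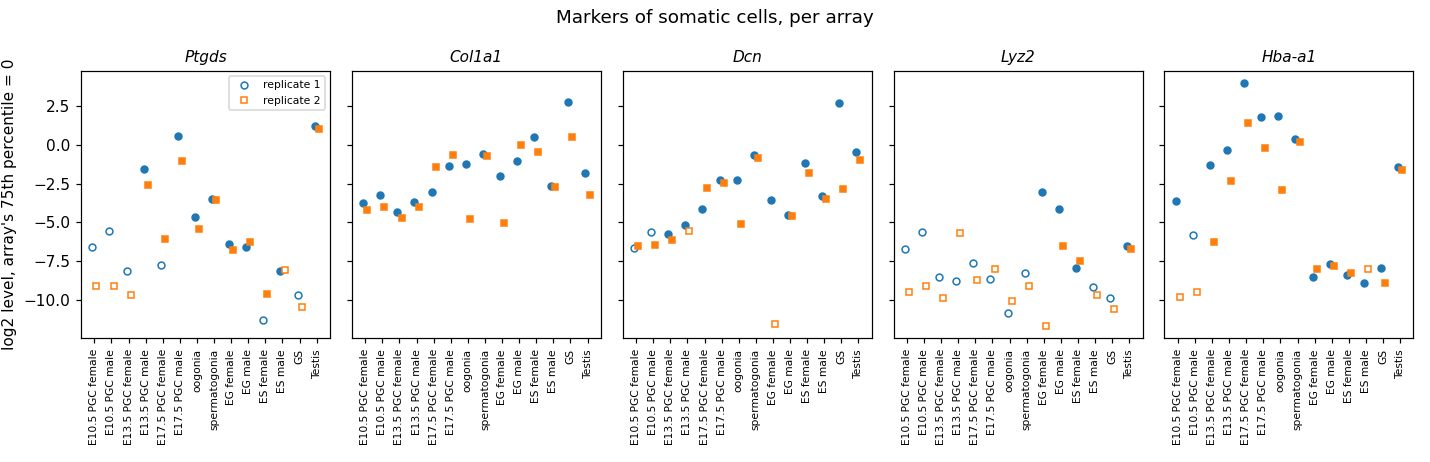
Level of 5 genes of somatic cells (log2 relative to each array's 75th percentile, vertical axis) on each of the 28 arrays, by group (horizontal axis), circles for replicate 1 and squares for replicate 2, hollow where not well above background. Ptgds lies at -1.56 and -2.61 in E13.5 males and at -8.15 and -9.68 in E13.5 females, and Dcn at 2.71 and -2.82 on the GS arrays.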

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

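Tests chosen only after the result was seen were those of other cells and of male RNA in EG female replicate 1, of the X-linked testis list there, and of testis somatic RNA in male PGC. The comparison of the EG and ES sex differences was also added then.

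The sex difference of PGC differed between stages by a test of the change itself (limma interaction, values as log2 change of the male minus female difference). Between E10.5 and E13.5 it moved towards males for Lefty1 (6.86), Nodal (4.10), Sox9 (4.07) and Clu (3.92). It moved towards females for Dmrtc2 (-6.35), Gata2 (-5.26), Rec8 (-4.78), Dmc1 (-4.77), Rhox9 (-2.78), Tex101 (-2.74), Rhox6 (-2.70) and Sycp3 (-2.62). For other genes at least 1 of the 4 groups was not well above background on either array, so their fitted values are no measured sizes: Lefty2 (7.92), Nanos2 (6.47), Ptgds (6.29), Slc7a3 (2.86), Irx3 (-3.43), Prom1 (-5.42), Phlda2 (-5.44) and Stra8 (-8.95). With slide as a fixed block limma called 0 genes for this step (1848 without adjustment), so none of these kept its call there, while scan day as a block gave 747. The X-linked shift moved by -0.49 (adjusted p = 0.208 with an estimated correlation).

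From E13.5 to E17.5 Rec8 moved by 8.76, from lower (-4.36) to higher (4.41) in males, and Rhox6 by 3.97 (-2.90 to 1.06). Stra8 moved by 9.76, from -8.31 to 1.45, and Grb10 by 5.10, from -1.61 to 3.49, where the 1.45 and the -1.61 did not pass. Moves towards males were also seen for Gata2 (6.45), Tfap2c (5.50), Dmrtc2 (5.32), Pou5f1 (3.83), Rhox9 (3.34), Dmc1 (2.72), Morc1 (2.59), Mcm7 (2.43), Dnmt3a (2.12), Rhox5 (1.94), Tdh (1.84) and Ccnb1 (1.5), and towards females for Sycp1 (-3.31) and Ifitm1 (-1.54). With at least 1 group not well above background, and so with fitted values that are no measured sizes, there were Phlda2 (11.30), Dnmt3l (7.61), Cdhr1 (7.24), Utf1 (7.20), Afp (6.63), Prom1 (6.2), Tie1 (6.07), Rbmy (6.04), Esrrb (3.59), Prdm1 (3.40), Prdm14 (3.08), Irx3 (2.88), Nanog (2.38), Lefty1 (-3.29), Nanos2 (-4.31), Lhx8 (-4.47), Nobox (-5.73), Lefty2 (-7.85) and Reg2 (-8.12).

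The sex difference also differed between EG and ES cells, in 338 of 19091 genes (195 higher and 143 lower in EG). Named genes with such a change were Mgp (8.51), Rhox6 (5.22), Rhox9 (4.56), Dppa3 (4.03), Kit (1.89) and Xlr5c (-6.67). At least 1 group was not well above background for Ubd (7.34), Reg2 (7.19), Smcr8 (6.81), Ncapg2 (6.77), Htr5a (-5.62), Cd300lf (-6.92) and Atp13a4 (-8.06). The ES lines differ in strain as well as sex, so strain and sex cannot be told apart for them.

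Sertoli genes were higher in male PGC at E13.5 and E17.5, for which RNA of testis somatic cells is a candidate explanation. Among members higher in males, replicate 1 exceeded replicate 2 by a median of 1.06 at E13.5 (5 of 6) and 0.94 at E17.5 (9 of 9), while the germ cell list moved by -0.26 and -0.25. Other somatic lists moved unevenly, Leydig genes by -0.39 (1 gene) and 0.68 (3 genes) and blood genes by 1.99 (1 gene) and 0.50 (4 genes). Scan day acting alike on genes of that level was argued against, since both medians lay at percentile 100 of 10000 random lists of like size and level. The germ cells' own expression of these genes was not tested and stays open, and the labels state no sort that would remove somatic cells.

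X-linked genes were lower in EG female replicate 1 than in replicate 2, with a shift of -0.53 log2 units against autosomal genes (317 genes), where the other 13 groups had shifts from -0.09 to 0.09. Male EG RNA was argued against (Eif2s3y at -6.45 relative to the male mean), and so were other cells as most of that RNA (pluripotency median 0.07). Fibroblast genes were nonetheless higher by 2.95. The germ cell list read -1.05 (quartiles -2.15 and -0.40), a difference that the test of X loss did not cover. Loss of 1 X chromosome in those cells may account for the general shift, which was at or under -0.32 in each of 4 equal blocks of the X-linked genes in gene order. An inactive X would lower the whole chromosome too, so the blocks cannot single out loss. Xist lay at -6.24 on replicate 1 and -7.43 on replicate 2, against -6.83 and -7.38 in EG males. X loss was argued against for the X-linked testis list, whose median of -3.45 (upper quartile -2.81) is below what losing 1 of 2 copies allows. Inactivation of 1 X, strain and culture passage were not tested.

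The counts of changed genes were set against other splits of the same arrays. For E13.5 against E10.5 1 of 35 splits, the real one, gave as many genes (1921 in a 2-group fit, highest other 1), and for E17.5 against E13.5 it was also 1 of 35 (940 genes, highest other 280, from the split by sex). Only 18 keep 2 arrays of each scan day per side (same highest others), too few for a share under 0.05. For EG against ES 1 of 35 gave as many (1472, highest other 23). These arrays lie on 2 slides, and with slide as a random block limma called 0 genes (399 without adjustment). For EG against PGC it was 1 of 100 drawn splits (4591, highest other 477, from the E10.5 arrays against the rest). All arrays are in groups of 2, and splits that part a pair are no fair reference, so chance stays open throughout. For EG these splits cannot tell cell type from slide or day.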

How the results depend on the processing

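Chosen only after results were seen were the percentile over all probes, the filter on any group, the scan-day block, the common floor and the fit without the libraries that stood apart. The X-linked shifts kept their sign under every alternative that gave a value. Of 1082 list values under the alternatives that kept all replicates or left out several, 973 kept their call, 39 fell short of the threshold, 67 newly passed and 3 reversed. Of 5067 values of named genes 4624 kept it, 439 fell short, 2 newly passed and 2 reversed. Counts of changed genes moved far more. Except where stated, the cause was not tested.

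Quantile normalization gave 3 genes for sex at E10.5, 623 for EG against ES, 112 for sex in EG and 451 for sex in ES. Normexp background correction gave 1507 for E13.5 against E10.5, 2509 for E17.5 against E13.5, 0 for sex at E10.5 (limma, 16 without adjustment), 328 at E13.5 and 3096 at E17.5. For the change of the sex difference it gave 15 and then 1152. It gave 559 for spermatogonia against E17.5 males, 14955 for EG against PGC, 332 for EG against ES, 68 for sex in EG, 236 for sex in ES and 13596 for GS against spermatogonia. The series matrix values gave 1090 for E13.5 against E10.5, 2220 for E17.5 against E13.5, 3927 for sex at E17.5, 98 and 1620 for the change of the sex difference, 182 for spermatogonia and 250 for oogonia against E17.5 PGC, 806 for EG against ES, 306 for sex in ES and 2806 for GS against spermatogonia. The percentile over all probes gave 287 for the change of the sex difference to E13.5.

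No filter on dim probes gave 1014 for sex at E13.5, 160 for the change of the sex difference to E13.5, 1099 for spermatogonia against E17.5 males, 20411 for EG against PGC, 700 for EG against ES, 91 for sex in EG, 363 for sex in ES and 10096 for GS against spermatogonia. The filter on any group gave 233 for the change of the sex difference to E13.5 and 14505 for EG against PGC. With a common floor the counts were 16 for sex at E10.5, 679 for the change of the sex difference to E13.5, 4690 for spermatogonia against E17.5 males and 4300 for EG against PGC. The count for EG against PGC thus depended on how dim probes were treated. A 2-fold minimum, stricter by construction, left 2187 for E13.5 against E10.5, 3811 for E17.5 against E13.5 and 5223 for EG against PGC.

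With eBayes with trend and robust the counts were 2 for sex at E10.5, 763 for the change of the sex difference to E13.5, 373 for sex in EG and 1130 for sex in ES. With only the groups of the comparison in the fit, which leaves fewer arrays to estimate the spread, E13.5 against E10.5 had 730, the change of the sex difference to E17.5 2027, EG against ES 4046, sex in ES 370 and GS against spermatogonia 2719. In that fit limma called 0 for sex at E10.5 (2 without adjustment), sex at E13.5 (1502), the change of the sex difference to E13.5 (832), spermatogonia (4493) and oogonia (3870) against E17.5 PGC and sex in EG (3620).

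Slide as a fixed block gave 839 for E13.5 against E10.5, 1755 for E17.5 against E13.5, 30 for sex at E13.5 and 2330 for the change of the sex difference to E17.5. It gave 0 for sex at E10.5 (limma, 44 without adjustment) and for the change to E13.5 (1848). It was not run for sex in EG, sex in ES and GS against testis, each of which lies on 1 slide. Scan day as a fixed block gave 747 for the change to E13.5. With the replicate block the list shifts numbered 97 (98 without it), and each count of changed genes stayed within 1.5 times its value. Slide as a random block gave 2848 for sex at E13.5, 1391 for the change to E13.5, 3669 for spermatogonia against oogonia, 165 for spermatogonia and 423 for oogonia against E17.5 PGC, 1836 for EG against PGC, 0 for EG against ES (limma, 399 without adjustment), 633 for sex in EG, 1833 for sex in ES and 868 for GS against spermatogonia. The libraries that stood apart left out gave 0 for sex at E10.5 (limma, 110 without adjustment), 3285 for spermatogonia against E17.5 males, 109 for sex in EG and 1605 for sex in ES.

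Reversed values were few. The pluripotency list of EG against ES, which did not pass in any case, reversed relative to other genes at medians of 0.04 with quantile normalization, 0.04 with series matrix values and 0.09 without ES male replicate 1 (0.19 at the other end of the range over left-out replicates). With normexp Kitl read -0.21 for E13.5 against E10.5, Junb -0.52 for GS against spermatogonia and the spermatogonial list -1.01 there, again relative to other genes.

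Leaving out each replicate in turn assumes that a lone array varies like the other groups. Counts ran from 3070 to 3899 for E13.5 against E10.5, 4496 to 5410 for E17.5 against E13.5, 0 (without E10.5 male replicate 1; limma, 74 without adjustment) to 43 for sex at E10.5, 636 to 1536 at E13.5 and 5351 to 5593 at E17.5. The change of the sex difference ran from 146 to 920 and from 3167 to 3725. Ranges were 5685 to 6157 for spermatogonia against oogonia, 401 (without spermatogonia replicate 1) to 958 against E17.5 males and 763 (without oogonia replicate 1) to 1824 for oogonia against E17.5 females. They were 6184 to 9148 for EG against PGC, 414 to 926 for EG against ES, 14 (without EG male replicate 1) to 419 for sex in EG, 133 to 201 for sex in ES, 2759 to 4924 for GS against spermatogonia and 8338 to 9598 for GS against testis. List shifts numbered 90 to 102. X-linked shifts ran from -0.15 to -0.04 at E10.5, -0.64 to -0.60 at E13.5, -0.65 to -0.57 at E17.5, -0.81 to -0.13 in EG (without female replicates 1 and 2) and -0.75 to -0.67 in ES. Of 424 list values 385 kept their call, 24 fell short, 14 newly passed and 1 reversed. For 2004 gene values the counts were 1738, 264, 2 and 0.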

Other observations

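Both tests of the GS arrays were chosen only after the result was seen. Immediate early and heat shock genes were higher in GS cells than in testis, 12 of 12, with a median of 4.71 (camera adjusted p = 2.79e-07, or adjusted p = 0.115 with an estimated correlation). Fos, the founding member of that class, lay at -0.86 and -1.91 on the GS arrays and at -8.40 and -8.48 on the testis arrays. This list was also higher on GS replicate 1 (median 1.64, 11 of 12), alongside the fibroblast genes below. From E13.5 to E17.5 9 of 12 Hox genes, which pattern the body axis, rose in PGC (median 2.01, adjusted p = 0.0483, or 0.579 with an estimated correlation). Fibroblast markers were higher in the same samples, with Col1a1 between -4.68 and -3.65 at E13.5 and between -3.02 and -0.63 at E17.5, and Dcn between -6.10 and -5.17 and then between -4.11 and -2.27. The haemoglobin gene Hba-a1 was higher on scan day 1 than on day 2 in E17.5 females (4.01 and 1.43) and in E17.5 males (1.78 and -0.22). The 2 oogonia arrays held it at 1.90 and -2.91, with the collagen Col1a1 at -1.24 and -4.78 and the mast cell protease Cma1 at -3.36 and -0.21.

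The 2 GS arrays had the lowest correlation of any replicate pair (0.940, against 0.997 in testis). Fibroblast genes were higher on replicate 1 by a median of 2.88 (12 of 13), with Col1a1 at 2.75 and 0.54. RNA of fibroblasts in replicate 1 may account for this, since the germ cell list was lower there by a shift of -0.67 and proliferation genes by -1.02 (0 of 20 higher). Brightness or scaling acting alike on genes of that level was argued against, since the fibroblast median lay at percentile 100 of 10000 random lists of like size and level (their 95th percentile was 0.47 and their highest 1.85). That test replaced one on the median of all genes, which scaling holds near 0. The labels name neither feeder cells nor a sort, and a change within the germ cells was not tested.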
